A study of Caenorhabditis elegans with 6 samples.

How the data were processed

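Messenger and other RNA levels were measured by RNA sequencing of whole Caenorhabditis elegans collected in the last larval stage, late L4, after growth at 20 °C. Per the labels' protocols, total RNA was isolated with an acid phenol reagent and spin columns, and libraries were made with a VAHTS Universal V8 kit. How messenger RNA was selected and whether the libraries keep strand are not given in the sources used here, so reads of a gene and of an antisense or overlapping partner cannot be told apart. The 2 strains had 3 libraries each. The labels do not say that replicates came from separate cultures, and p-values then measure only the spread between these libraries, which may be technical.

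The submitters' processing notes name FastQC 0.11.5, TopHat2, HTSeq and DESeq2 without saying what each was used for, and they name no genome build. The authors deposited 1 gene table per library in the layout that Cufflinks writes. Each lists 46245 genes with an FPKM (fragments per kilobase of transcript, scaled to the library's mapped fragments), a lower and an upper bound and a status word, per the file headers. These are normalised values and not counts, so the count models planned before the data were examined (edgeR, with DESeq2 as an alternative) were not used, and limma took their place. The files' coordinates start at 0 and were raised by 1. Of 46245 genes, 45990 matched an identifier in the Ensembl 115 annotation of WBcel235. All of these lay on the same chromosome, 62.3% had the same start and end, and 97.7% lay within 1000 bp, so positions are given as the files give them. Gene names are current symbols from the name table where these are unique, and the files' names elsewhere.

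Depth was not stated. The half-width of each FPKM interval was read as 2 standard errors, which gives an implied fragment number per gene. Among genes with 1 transcript and up to 30 implied fragments, 80.7% to 82.7% of these numbers per library lay within 0.1 of a whole number. Relative depth came from 3401 protein-coding genes with 1 transcript, under a higher limit on implied fragments that was met in every library. It was 1, 1.55 and 0.569 in the eat-2; acs-20 libraries (replicates 1 to 3) and 1.11, 1.25 and 0.991 in the ptr-8 eat-2; acs-20 libraries. The median implied number over genes was 353, 447 and 185 fragments in the first strain and 367, 510 and 297 in the second, and the median interval half-width ran from 8.85% to 14.7% of the FPKM. These intervals do not cover the spread between libraries, and whether they hold counting error alone is not known. The log2 fold change of asp-12 was -4.48 from implied fragments and -7.43 from FPKM, so implied numbers are not plain counts.

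The deposited FPKM values were divided by a factor per library, the exponent of a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed at each end). The factors ran from 0.870 to 1.33. Genes needed a scaled FPKM of at least 1 in 3 libraries. Loci under 200 bp (22932 of those listed) and 10 genes that the files mark FAIL in any library, vit-2 among them, were left out of all tests. This left 15207 genes. limma 3.58.1 (R 4.3.3, intensity trend on) was fitted to log2(scaled FPKM + 1), strain as the only term, all 6 libraries. Fold changes are ptr-8 eat-2; acs-20 minus eat-2; acs-20 on that scale, which understates the change of genes with low FPKM. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Data were simulated from each gene's mean and spread and the libraries' scaling factors (15058 genes, 200 of them changed). On these the procedure recovered 61% of 2-fold and 85% of 4-fold changes, and 3.31% of its calls were false. The noise was drawn independently for each gene, and the changed genes were not drawn from the lowest levels. These rates may therefore not hold for the real libraries, where genes vary together.

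Gene lists and the rule for named genes were fixed before the data were examined. Of 44 lists, 43 had at least 3 tested genes. They were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated from the data, and with fry, each adjusted over all lists. fry asks whether a list's genes move on balance one way and does not compare the list with other genes. A mixed form of fry, given where named, counts movement in either direction, also without comparison with other genes. The genes named are the 3 of the genotypes, the 12 highest rises and 12 deepest falls among called genes with a lettered gene name, a mean log2 level of at least 1 and no overlap between strains, and up to 4 genes of lowest p per list. The mean level was planned on a count scale and applied to log2(scaled FPKM + 1). Any other gene is said to have been chosen after its values were seen. Alternatives tried were median-of-ratios and upper-quartile scaling, no filter, a pseudocount of 0.1, a replicate block and each library left out in turn. Added after the data were seen were FPKM as deposited, limma voom on implied fragments, both libraries that stand apart left out together, and the level of adult-stage collagens as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.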

Results

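Gene expression was compared between 2 C. elegans strains at late L4, with 3 libraries per strain. The reference strain carried eat-2(ad465) and acs-20(tm3232). eat-2 encodes a nicotinic acetylcholine receptor subunit of the pharynx, and its mutants feed slowly and serve as a model of dietary restriction. acs-20 encodes an acyl-CoA synthetase of the fatty acid transport protein family. The second strain carried ptr-8(mkc18) as well, a mutation in a gene for a patched-related membrane protein. The comparison therefore asked which transcripts differ when ptr-8 is mutated in the eat-2; acs-20 background. Between 14883 and 15461 genes per library reached an FPKM of 1. Replicate 3 of eat-2; acs-20 was the shallowest library, at 0.569 times the depth of replicate 1, and replicate 2 of the ptr-8 strain needed the largest scaling factor, 1.33. Correlations across genes of log2 levels were 0.961 to 0.975 within eat-2; acs-20, 0.962 to 0.981 within the ptr-8 strain and 0.939 to 0.969 between strains. Values are mean scaled FPKM ± SD over n = 3 libraries per strain, eat-2; acs-20 first, and adjusted p-values are from limma unless a list test is named.

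ptr-8 (WBGene00004222, chromosome II, 10889279 to 10893277, plus strand, 11 exons) was itself lower in the strain that carries mkc18. Its level was 21.8 ± 3.23 in eat-2; acs-20 and 5.11 ± 0.608 in the ptr-8 strain, 23.5% of the first (log2 fold change -1.89, SE 0.15, adjusted p = 0.00547), and it passed with each library left out in turn. acs-20 (WBGene00009218, chromosome IV, 12392123 to 12398706) was at 62.2 ± 11.1 and 47.8 ± 4.25 and did not pass (log2 fold change -0.36, SE 0.16, adjusted p = 0.263). eat-2 (WBGene00001133, chromosome II, 14166882 to 14171648) lay between 0 and 0.205 deposited FPKM in all 6 libraries and was not tested. The parts of ptr-8 and acs-20 that the alleles remove are not given in the sources used here, so a level over the whole gene does not check the alleles.

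Most of the called genes were lower in the ptr-8 strain. Of 15207 genes, 366 passed, and 313 of these were lower and 53 higher in the ptr-8 strain. Rises made up 14.5% of these calls, but 40.9% (275 higher, 398 lower) without eat-2; acs-20 replicate 1, 30.3% (27 and 62) without its replicate 2 and 28.6% (18 and 45) without its replicate 3. The share was 15.9%, 13.9% and 17.1% without ptr-8 strain replicates 1, 2 and 3. Falls to near 0 in the ptr-8 strain miss the filter on level without an eat-2; acs-20 library, so these shares rest on different genes. Of the 366, 355 were protein-coding. At least a 2-fold change was seen in 230, of which 193 were lower and 37 higher. asp-12, of the aspartyl protease family, went from 1346 ± 368 to 6.88 ± 2.47 (log2 fold change -7.43, SE 0.28, adjusted p = 0.000631). With voom on implied fragments its log2 fold change was -4.48, less deep than those of spp-12, ech-9 and clec-70 in that fit. ech-9, of the enoyl-CoA hydratase family, went from 145 ± 59.6 to 0.571 ± 0.320 (log2 fold change -6.48), and the C-type lectin gene clec-70 from 113 ± 40.8 to 0.630 ± 0.364 (-6.09). The glucuronosyltransferase gene ugt-18 went from 36.8 ± 16.7 to 0.277 ± 0.172 (-4.81). nspg-7.2, clc-11, tsp-2, tsp-1, sru-40, dod-22 and clec-71 fell by 2.90 to 3.60 on the log2 scale (adjusted p between 0.00224 and 0.00933). tsp-1 and tsp-2 are neighbouring tetraspanin genes of similar sequence, and the split of reads between them is uncertain. The saposin-like gene spp-12 was at 56.0, 50.8 and 77.2 in the eat-2; acs-20 libraries and is listed at 0 in all 3 ptr-8 libraries (adjusted p = 0.000400). Gene-level FPKM does not show whether a gene listed at 0 in a whole strain is silent or missing from that strain's genome.

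Fewer genes rose. The yolk protein gene vit-3 went from 7.62 ± 5.25 to 62.5 ± 6.49 (log2 fold change 3.12, SE 0.53, adjusted p = 0.0461) and vit-1 from 6.71 ± 3.90 to 49.8 ± 3.99 (2.87, SE 0.41, adjusted p = 0.0292). The thaumatin-family gene thn-1 went from 1.56 ± 0.444 to 18.6 ± 2.31 (2.95, SE 0.18, adjusted p = 0.00413) and thn-2 from 45.7 ± 18.2 to 192 ± 22.6 (2.11, adjusted p = 0.0213). sod-5, a superoxide dismutase gene, went from 0.412 ± 0.509 to 5.23 ± 0.916 (2.19, adjusted p = 0.0213). The amino acid transporter gene aat-8, ugt-53, lys-10, drd-5, lys-5, bbs-4 and the autophagy gene atg-10 rose by log2 fold changes of 1.67 to 2.00 (adjusted p between 0.00939 and 0.0383). Of the 12 rises only thn-1 passed with each library left out in turn, and 10 of the 12 falls passed in each such fit that tested them. Of these 10 falls, spp-12, ech-9, clec-70, ugt-18, nspg-7.2 and clc-11 were not tested without an eat-2; acs-20 library, since they then miss the filter on level, so rises and falls were not tested in the same fits. Among the rises, bbs-4 was tested in only 3 of the fits with 1 library left out and sod-5 in only 4. tsp-1 failed without eat-2; acs-20 replicate 2 (adjusted p = 0.0578) or ptr-8 strain replicate 1 or 3, and clec-71 without eat-2; acs-20 replicate 3 (0.0519). The highest adjusted p of the other rises came without ptr-8 strain replicate 3 for sod-5 (0.105), ugt-53 (0.155), lys-10 (0.101) and drd-5 (0.157), without eat-2; acs-20 replicate 3 for aat-8 (0.103), lys-5 (0.0670), bbs-4 (0.0544) and atg-10 (0.0713) and without eat-2; acs-20 replicate 2 for thn-2 (0.0936). lys-10 and thn-2 passed only without eat-2; acs-20 replicate 1, drd-5 only without eat-2; acs-20 replicate 2 and ugt-53 only without eat-2; acs-20 replicate 1 or 3. aat-8 failed without replicate 2 or 3 of either strain, atg-10 without eat-2; acs-20 replicate 2 or 3 or ptr-8 strain replicate 1, lys-5 without eat-2; acs-20 replicate 3 or ptr-8 strain replicate 1, bbs-4 without eat-2; acs-20 replicate 2 or 3 and sod-5 without replicate 3 of either strain.

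**Figure D1:**
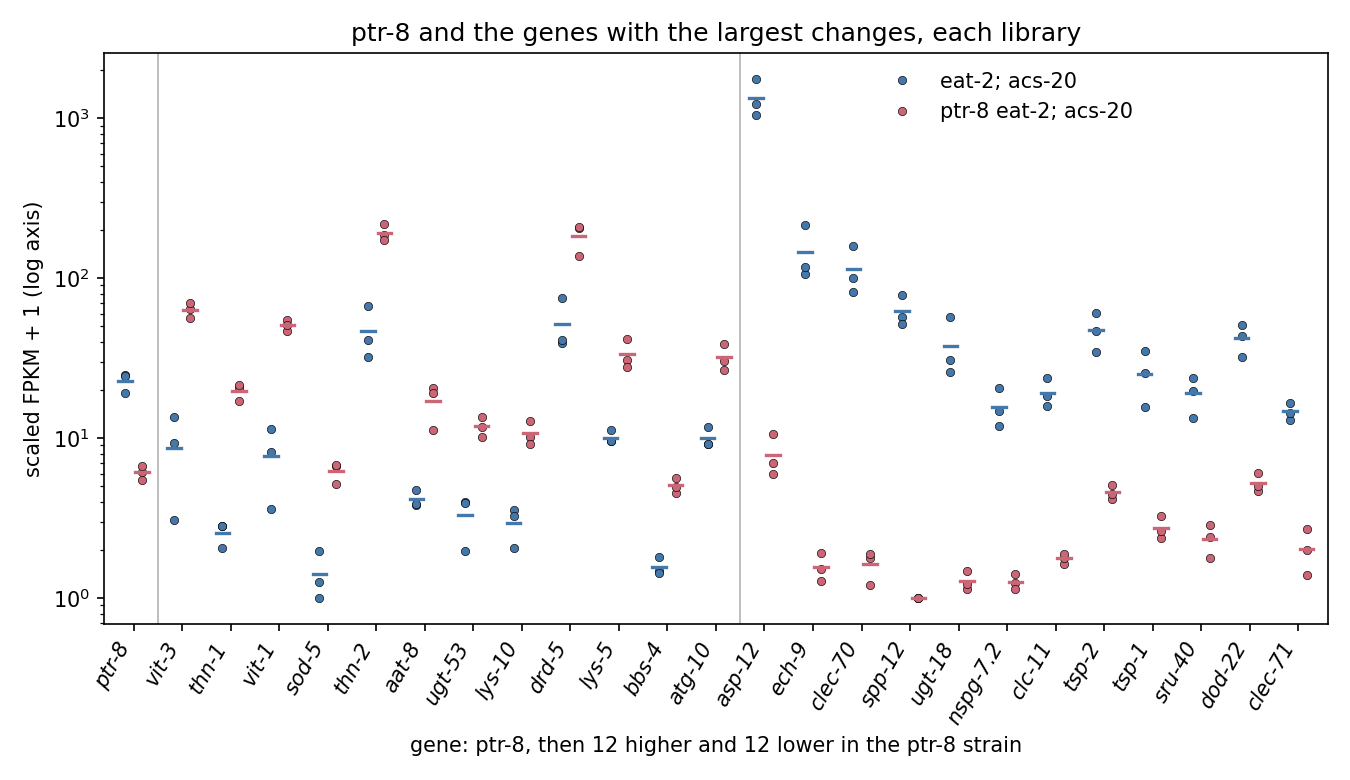
Scaled FPKM plus 1 (log axis) of ptr-8 and of the 12 highest rises and 12 deepest falls, 1 point per library and a short line at the strain mean, blue for eat-2; acs-20 and red for ptr-8 eat-2; acs-20. The strains do not overlap at any of these genes, and spp-12 sits at the floor in the ptr-8 strain, where it is listed at 0.

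**Figure D2:**
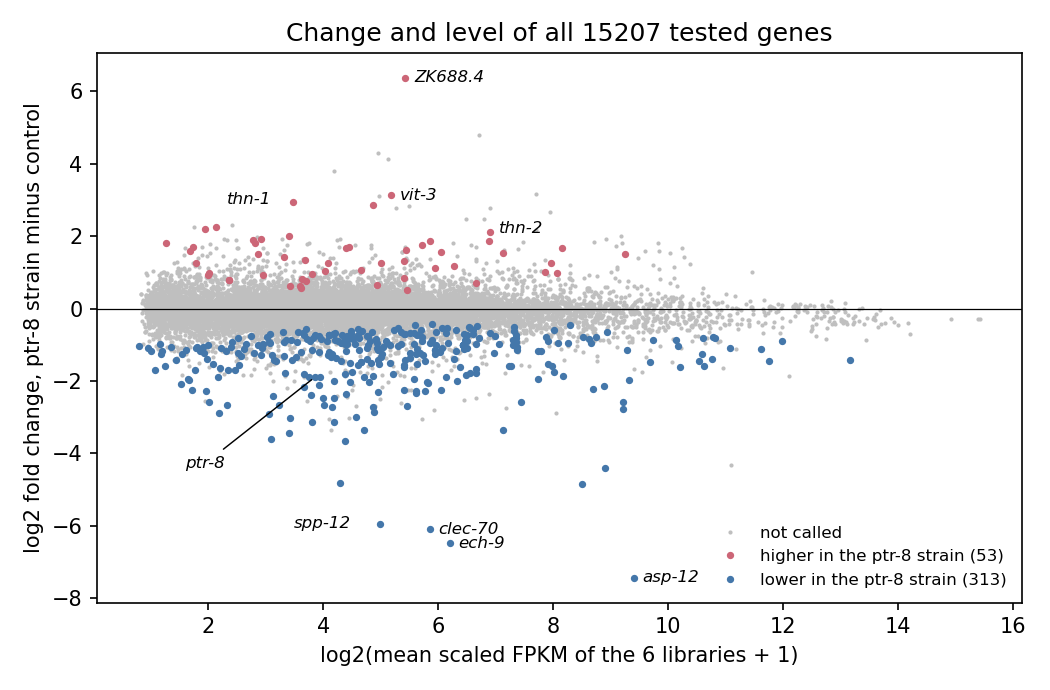
Log2 fold change (ptr-8 strain minus eat-2; acs-20) against the log2 mean level of the 15207 tested genes, 1 point per gene, with 53 called rises in red, 313 called falls in blue and the rest grey. Of these points asp-12 lies lowest, at -7.43.

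Intestinal immune effectors, C-type lectins and pals genes were lower as lists, and lysozymes went both ways. Among 14 tested intestinal immune effectors, 6 fell and 1 rose. Adjusted over the list alone, 13 were lower and 1 higher. dod-22 went from 41.2 ± 9.54 to 4.24 ± 0.694, clec-67 from 50.7 ± 5.28 to 6.33 ± 2.22, clec-60 from 29.6 ± 1.12 to 3.83 ± 1.33 and clec-85 from 76.0 ± 8.67 to 40.9 ± 3.72 (log2 fold changes -2.99, -2.86, -2.71 and -0.87; adjusted p between 0.00413 and 0.0251). The riser was the lysozyme gene lys-7, from 154 ± 27.6 to 307 ± 19.9 (1.00, adjusted p = 0.0295). The list's median was -1.43, with camera adjusted p = 5.27e-09 and fry adjusted p = 0.0128, and adjusted p = 0.351 with an estimated correlation. Of 117 C-type lectin genes, 23 fell and 1, clec-7, rose. Adjusted over the list alone, 38 were lower and 2 higher (median -0.24, camera adjusted p = 1.69e-05, fry adjusted p = 0.00411, adjusted p = 0.275 with an estimated correlation). They included clec-52 (109 ± 8.76 to 28.97 ± 2.48), clec-62 (153 ± 20.3 to 47.2 ± 3.77) and clec-174 (5.46 ± 0.391 to 0.339 ± 0.154), and 3 genes belong to both lists. Of 18 genes of the pals family, many of which respond to intracellular pathogens, pals-24 (62.3 ± 2.03 to 20.7 ± 3.44), pals-23 and pals-37 fell and none rose. Another count, adjusted over the list alone, was 10 lower and 0 higher (median -0.65, camera adjusted p = 1.77e-07, fry adjusted p = 0.00411, adjusted p = 0.275 with an estimated correlation). Lysozyme genes split: of 13, lys-3, ilys-4, lys-2 and lys-8 fell (lys-3 from 22.1 ± 2.53 to 3.50 ± 0.923), while lys-5, lys-10 and lys-7 rose. Counts were 5 lower and 3 higher adjusted over the list alone. The lysozyme list passed neither camera (adjusted p = 0.439) nor fry (0.0679), but the mixed form of fry called it (adjusted p = 0.000138). Without eat-2; acs-20 replicates 1, 2 and 3, lysozyme falls numbered 5, 2 and 2 and rises 4, 1 and 0. Without ptr-8 strain replicates 1, 2 and 3, falls numbered 2, 3 and 2 and rises 0, 1 and 1. Among 17 epidermal antimicrobial peptide genes, cnc-2 fell from 1767 ± 238 to 593 ± 174 (adjusted p = 0.0330), and nlp-29 was at 3137 ± 256 and 1471 ± 416 without passing (adjusted p = 0.0621). Adjusted over the list alone, 6 were lower (median -0.83, camera adjusted p = 0.000454, fry adjusted p = 0.0494, adjusted p = 0.484 with an estimated correlation). clec-7, lys-8, vit-2, acdh-2, ugt-43 and ugt-64 lie outside the rule for named genes and were chosen after their values were seen. The number of C-type lectin genes that fell was 22, 7 and 5 without eat-2; acs-20 replicates 1, 2 and 3 and 8, 15 and 7 without ptr-8 strain replicates 1, 2 and 3, and 10 with voom on implied fragments. For immune effectors it was 9 without eat-2; acs-20 replicate 1 and 3 without any other 1 library. With 1 library left out, clec-85 (0.116), lys-7 (0.134), pals-23 (0.134), pals-37 (0.164) and cnc-2 (0.143) reached their highest adjusted p without eat-2; acs-20 replicate 3 and lys-2 (0.103) without ptr-8 strain replicate 3. Each of these also failed without eat-2; acs-20 replicate 2 and ptr-8 strain replicate 3, all but pals-23 without ptr-8 strain replicate 1, and clec-85, lys-7 and pals-37 without ptr-8 strain replicate 2. The call of lys-2 failed without eat-2; acs-20 replicate 3 as well. clec-52, clec-60, clec-62, clec-67, dod-22, lys-3, ilys-4 and pals-24 passed with each library left out in turn. In the same libraries the adult-stage collagens, a stage marker, had mean log2 levels of 8.22, 7.27 and 6.29 in eat-2; acs-20 and 8.68, 8.23 and 8.62 in the ptr-8 strain.

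Yolk protein genes were higher in the ptr-8 strain. All 5 tested vitellogenin genes were higher adjusted over the list alone, and 2, vit-1 and vit-3, rose over all genes (median 2.78, camera adjusted p = 5.52e-05, fry adjusted p = 0.0494, adjusted p = 0.471 with an estimated correlation). vit-5 was at 33.8 ± 20.1 and 202 ± 28.1 and vit-4 at 10.9 ± 8.78 and 63.5 ± 7.31, neither passing over all genes. vit-1 no longer passed without any 1 of the ptr-8 strain replicates (highest adjusted p 0.117, without replicate 3), nor did vit-3 without these or eat-2; acs-20 replicate 1 or 2 (highest 0.173, without ptr-8 strain replicate 3). The genes vit-3, vit-4 and vit-5 are close copies whose reads can be exchanged. vit-2, which was not tested, was at 186 ± 116 and 650 ± 82.6. None of 20 oogenesis genes passed over all genes in limma (18 at unadjusted p below 0.05), and 18 were higher adjusted over the list alone (median 0.77, camera adjusted p = 5.15e-09, fry adjusted p = 0.133, adjusted p = 0.484 with an estimated correlation). Of these oma-1 was at 20.7 ± 4.69 and 35.4 ± 5.21. Camera also called 20 germline genes (median 0.17, adjusted p = 0.000471), 53 sperm genes (0.23, adjusted p = 0.00877) and 33 major sperm protein genes (0.36, adjusted p = 0.0103) higher, with no member passing in limma over all genes or adjusted over the list alone (6, 2 and 1 at unadjusted p below 0.05). Their adjusted p was 0.720, 0.776 and 0.776 with an estimated correlation and 0.235, 0.681 and 0.681 with fry. The germline median was 0.09 without eat-2; acs-20 replicate 2 (adjusted p = 0.0300). The sperm gene median was 0.42, 0.07 and 0.15 without eat-2; acs-20 replicates 1, 2 and 3 and 0.07, 0.38 and 0.14 without those of the ptr-8 strain. For major sperm proteins it was 0.76, 0.18 and 0.16 without eat-2; acs-20 replicates 1, 2 and 3, and 0.17 and 0.63 without ptr-8 strain replicates 1 and 2. The sperm gene call was lost without eat-2; acs-20 replicate 2 (adjusted p = 0.384) and without ptr-8 strain replicate 1, and that of the major sperm proteins without eat-2; acs-20 replicate 2 or 3 or ptr-8 strain replicate 1 (highest adjusted p 0.361). With the level of adult-stage collagens as a covariate the direction turned, to a median of -0.10 for sperm genes and -0.55 for major sperm proteins. The 4 genes listed as adult-stage collagens, col-19, col-62, col-7 and col-63, had mean log2 levels of 8.22, 7.27 and 6.29 in the eat-2; acs-20 libraries and 8.68, 8.23 and 8.62 in the ptr-8 strain. The most abundant of them, col-63, went against the other 3: it was at 879, 1095 and 1290 in eat-2; acs-20 and at 861, 937 and 964 in the ptr-8 strain, while col-19 was at 424, 217 and 74.5 and at 738, 590 and 850. Whether col-63 marks the same stage as the other 3 was not tested, so its course does not count against a later stage in the ptr-8 strain. None of the 4 passed in limma (2 at unadjusted p below 0.05), and the list did not (median 1.65, camera adjusted p = 0.168, fry adjusted p = 0.158). Replicate 3 of eat-2; acs-20, lowest in these collagens, was also lowest in vitellogenins (mean log2 level 3.02, against 4.83 and 5.08 in replicates 1 and 2) and in oogenesis genes (4.25, against 5.13 and 4.96), whereas replicate 1 was above replicate 2 in the collagens and below it in vitellogenins. Replicate 1 of eat-2; acs-20 and replicate 2 of the ptr-8 strain had nearly equal collagen levels (8.22 and 8.23), and vit-3 was at 8.33 in the first and 63.4 in the second. This pair is 1 library per strain, chosen after the values were seen. Within it col-19 was at 424 in the first and 590 in the second, so the 2 libraries may still differ in stage.

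**Figure D3:**
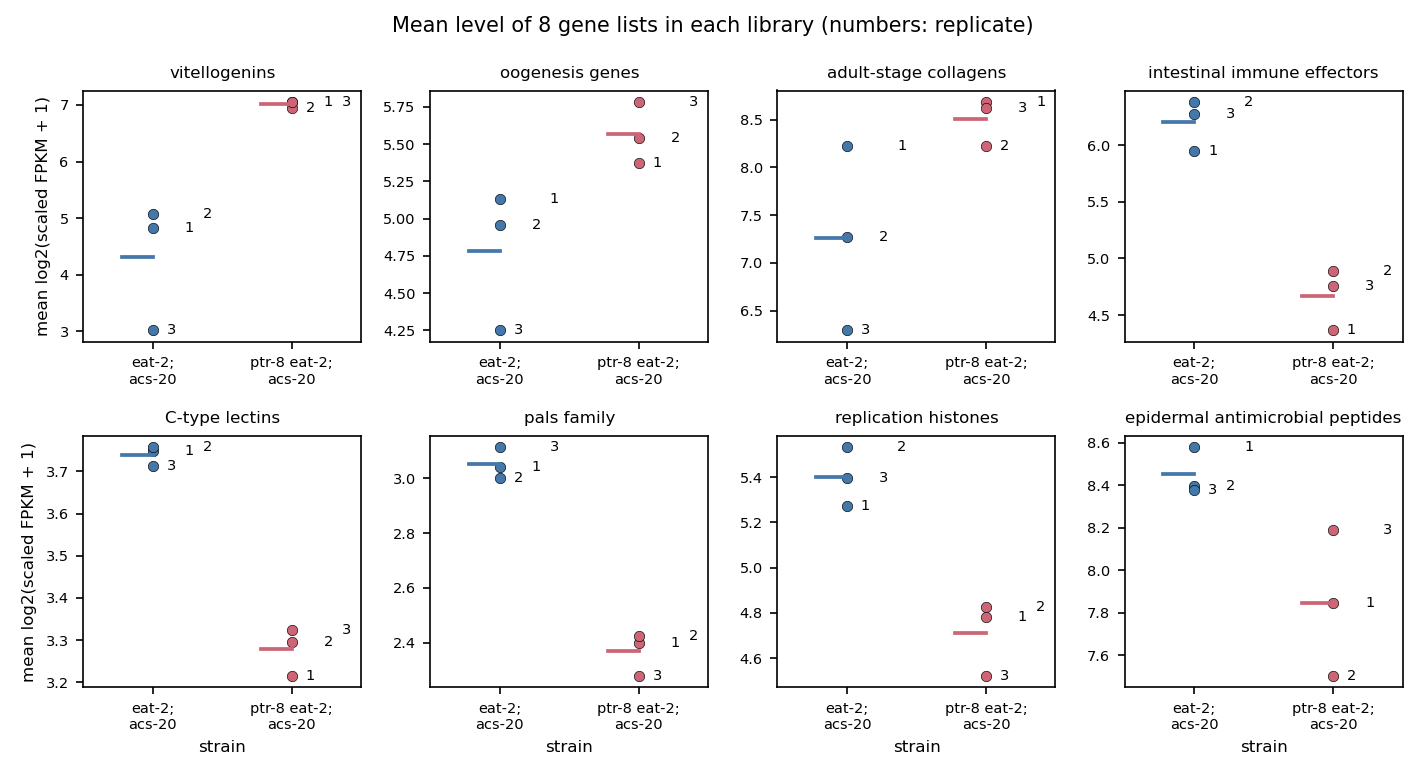
Mean log2(scaled FPKM + 1) over the tested genes of 8 lists, 1 point per library (numbered by replicate) and a short line at the strain mean, each panel on its own scale that does not start at 0. Vitellogenins and oogenesis genes are higher and immune lists, pals genes and histones lower in all 3 ptr-8 libraries, while adult-stage collagens range from 6.29 to 8.22 among the eat-2; acs-20 libraries.

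Lipid genes gave single calls in several pathways. In sphingolipid metabolism, 3 of 27 genes fell: hyl-1, a ceramide synthase (85.5 ± 2.27 to 53.5 ± 4.81, log2 fold change -0.67), ttm-5, a sphingolipid desaturase (33.5 ± 4.51 to 19.4 ± 1.45, -0.75), and cgt-1, a ceramide glucosyltransferase (22.8 ± 3.71 to 8.86 ± 2.58, -1.296). Adjusted over the list alone 9 were lower and none higher (median -0.15, camera adjusted p = 0.00877, fry adjusted p = 0.0275, adjusted p = 0.351 with an estimated correlation). The sphingolipid median was -0.10 without eat-2; acs-20 replicate 2 and -0.09 without ptr-8 strain replicate 1, and -0.04 on the FPKM as deposited. No gene of the list fell on these values (limma, p adjusted over all genes) or with voom on implied fragments, and 1 did with upper-quartile scaling. Without eat-2; acs-20 replicate 1 the number was 3, and without any other 1 library 0. Of 37 fatty acid oxidation genes, ech-9, acox-1.5 (91.0 ± 49.2 to 16.3 ± 1.76), acdh-6 and acdh-10 fell and acdh-2 rose, with 7 lower and 1 higher adjusted over the list alone. The median of that list was 0.02 while its mean was -0.23, and it passed neither camera (adjusted p = 0.312) nor fry (0.235). The mixed form of fry called it (adjusted p = 0.000156). Among 21 genes of fatty acid synthesis, desaturation and elongation only fat-5, a palmitate desaturase, changed (41.3 ± 9.497 to 13.7 ± 0.908, -1.501, adjusted p = 0.0142), over all genes and adjusted over the list alone (median -0.01, camera adjusted p = 0.842 with direction up, fry 0.807). The mixed form of fry called that list too (adjusted p = 3.66e-05). Of 22 acyl-CoA synthetase genes, acs-7 (38.1 ± 10.4 to 13.8 ± 2.57) and acs-11 fell, and acs-22, of the same family branch as acs-20, was at 82.6 ± 4.05 and 58.0 ± 8.32 without passing (adjusted p = 0.0989). Adjusted over the list alone 3 were lower. Here fry called the list (adjusted p = 0.00990), camera did not (0.380), and its median of -0.06 turned to 0.05 on the FPKM as deposited. lipl-1, a lysosomal lipase gene, fell from 34.1 ± 2.30 to 5.997 ± 2.25 (adjusted p = 0.00855), the only one of 9 lipases over all genes and 1 of 3 adjusted over the list alone (camera adjusted p = 0.0965, fry 0.0679). None of 9 fatty acid binding protein genes passed over all genes in limma (3 at unadjusted p below 0.05). Among them lbp-5 was at 408 ± 42.4 and 242 ± 36.9 (adjusted p = 0.0639) and was the 1 lower adjusted over the list alone. The binding protein list had median -0.45, camera adjusted p = 0.0245, fry adjusted p = 0.0367 and adjusted p = 0.351 with an estimated correlation, and camera lost it without eat-2; acs-20 replicate 2 (adjusted p = 0.0531) or ptr-8 strain replicate 2. With 1 library left out, the highest adjusted p was 0.131 for hyl-1, 0.177 for cgt-1, 0.155 for acdh-6 and 0.0544 for lipl-1 (without eat-2; acs-20 replicate 3), 0.180 for ttm-5, 0.188 for acdh-10, 0.0756 for fat-5, 0.149 for acs-7 and 0.190 for acs-11 (without ptr-8 strain replicate 3) and 0.120 for acox-1.5 (without ptr-8 strain replicate 1). Each of them except acox-1.5 failed without either of eat-2; acs-20 replicates 2 and 3, and all failed without ptr-8 strain replicate 3. The call of acox-1.5 failed without eat-2; acs-20 replicate 2 as well, and cgt-1 without eat-2; acs-20 replicate 1. Without ptr-8 strain replicate 1 all but lipl-1 failed, and without ptr-8 strain replicate 2 all but lipl-1 and fat-5. ech-9 passed in the 3 such fits that tested it.

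Histone genes, taken by the name his and not limited to replication-dependent ones, formed the list with the lowest camera p. Of 67, 13 fell and none rose, and 42 were lower adjusted over the list alone (median -0.71, camera adjusted p = 8.41e-19, fry adjusted p = 0.0189, adjusted p = 0.351 with an estimated correlation). his-1 went from 14.6 ± 3.34 to 3.52 ± 0.875, his-40 from 14.98 ± 2.84 to 4.94 ± 0.978, his-60 from 133 ± 9.17 to 67.7 ± 11.8 and his-22 from 20.4 ± 2.33 to 11.8 ± 0.570. Many of these genes are near-identical copies, so single members are uncertain and their number is not a number of independent genes. The number that fell was 21, 0 and 1 without eat-2; acs-20 replicates 1, 2 and 3, and 2, 3 and 0 without ptr-8 strain replicates 1, 2 and 3. It was 5 with upper-quartile scaling, 2 on the FPKM as deposited and 0 with voom on implied fragments, while 61 to 64 of the tested genes had negative fold changes in each of these fits. With 1 library left out, his-1 failed without eat-2; acs-20 replicate 2 or ptr-8 strain replicate 2 or 3 (highest adjusted p 0.0886), and his-40 (0.116), his-60 (0.124) and his-22 (0.136) failed without these or eat-2; acs-20 replicate 3, his-40 and his-22 also without ptr-8 strain replicate 1. The list's mean log2 level was 5.27, 5.53 and 5.40 in eat-2; acs-20 and 4.78, 4.82 and 4.52 in the ptr-8 strain, where the adult-stage collagens were at 8.22, 7.27 and 6.29 and at 8.68, 8.23 and 8.62.

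Among genes of the ptr-8 family and of the epidermis, few passed. Of 28 patched-related genes, ptr-8 itself and ptr-22 (23.9 ± 4.55 to 12.4 ± 1.06, adjusted p = 0.0489) fell, the same 2 adjusted over the list alone. That list includes the mutated gene ptr-8 and was not tested without it. It had median -0.21, camera adjusted p = 0.0217, adjusted p = 0.660 with an estimated correlation and fry adjusted p = 0.158. Camera lost the list without eat-2; acs-20 replicate 2 or ptr-8 strain replicate 1 (highest adjusted p 0.163). Its median was -0.34 without eat-2; acs-20 replicate 1 and -0.12 and -0.31 without ptr-8 strain replicates 1 and 2. Of 39 hedgehog-related ligand genes, wrt-8 fell (13.2 ± 3.19 to 4.66 ± 0.493, adjusted p = 0.0328), the 1 also lower adjusted over the list alone, and grd-5 was at 1223 ± 43.1 and 924 ± 43.2 without passing (0.0977). The ligand list had median -0.28, camera adjusted p = 0.00344, adjusted p = 0.484 with an estimated correlation and fry adjusted p = 0.131, and camera lost it without eat-2; acs-20 replicate 2 (adjusted p = 0.0539). No member passed, over all genes or adjusted over the list alone, among 134 cuticle collagens (camera adjusted p = 0.946), 6 furrow collagens (0.697), 24 cuticlins (0.0580), 25 molting genes (0.141), 8 heterochronic genes (0.975) or 12 epidermal markers (0.697), and fry gave adjusted p of at least 0.267 for each. Unadjusted p was below 0.05 in limma for 53, 0, 4, 4, 1 and 0 of them. The cuticle collagens went both ways (median -0.09, mean 0.21; 35 higher and 18 lower at unadjusted p below 0.05), col-142 being at 123 ± 41.8 and 279 ± 31.2 (adjusted p = 0.0908), and the heterochronic list had median -0.02 with camera direction up. ptr-22 and wrt-8 passed only without eat-2; acs-20 replicate 1 when 1 library was left out (highest adjusted p 0.186 without ptr-8 strain replicate 3 and 0.1399 without eat-2; acs-20 replicate 3).

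Genes of detoxification and stress were examined as lists. Of 58 UDP-glucuronosyltransferase genes, ugt-18, ugt-44 (80.7 ± 13.4 to 15.1 ± 1.63), ugt-17, ugt-31 and ugt-43 fell and ugt-53 and ugt-64 rose. With p adjusted over the list alone, 12 were lower and 4 higher (median -0.26, camera adjusted p = 0.00279, fry adjusted p = 0.0419, adjusted p = 0.471 with an estimated correlation). None of 58 cytochrome P450 genes passed over all genes in limma (20 at unadjusted p below 0.05), and 6 were lower and 3 higher adjusted over the list alone (median -0.25, camera adjusted p = 0.00270, fry adjusted p = 0.0494, adjusted p = 0.351 with an estimated correlation). Of 36 glutathione S-transferase genes gst-28 fell (61.0 ± 0.651 to 40.5 ± 4.41), 1 of 2 adjusted over the list alone (camera adjusted p = 0.329, fry 0.449). sod-5 and lys-7 rose among 14 DAF-16 targets, and adjusted over the list alone these 2 were higher and 3 lower (camera adjusted p = 0.7495, fry 0.792). The mixed form of fry called the DAF-16 targets (adjusted p = 2.81e-05). The 9 genes of the endoplasmic reticulum unfolded protein response had median -0.29 with none passing in limma over all genes or adjusted over the list alone (5 at unadjusted p below 0.05, camera adjusted p = 0.00205, fry adjusted p = 0.0896, adjusted p = 0.484 with an estimated correlation). hsp-16.2 was at 15.6 ± 14.4 and 2.69 ± 1.17, and the 15 heat shock genes (median -1.01, camera adjusted p = 0.118), 6 osmotic stress genes (0.266) and 9 genes of the mitochondrial unfolded protein response (0.439) did not pass, and no member of them did over all genes in limma (1, 1 and 0 at unadjusted p below 0.05). Of the osmotic list, hmit-1.1 was higher adjusted over the list alone. atg-10 was the only one of 27 autophagy genes to change, over all genes and adjusted over the list alone (median -0.07, mean 0.01, camera adjusted p = 0.499). With 1 library left out, gst-28 failed in each of the 6 fits (highest adjusted p 0.176), ugt-17 (0.1098) and ugt-31 (0.117) in all but that without eat-2; acs-20 replicate 1, and ugt-44 in none. The number of glucuronosyltransferase genes that fell was 5, 2 and 1 without eat-2; acs-20 replicates 1, 2 and 3 and 2, 2 and 3 without ptr-8 strain replicates 1, 2 and 3. The median of these genes was -0.17 without eat-2; acs-20 replicate 1, and that of the cytochrome P450 genes -0.16 without its replicate 2.

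Neuropeptide genes, markers of other tissues and genes of basic functions held 1 called gene, asp-1. None of 30 FMRFamide-like neuropeptide genes passed in limma over all genes or adjusted over the list alone (12 at unadjusted p below 0.05), with 26 at negative fold changes (median -0.29, camera adjusted p = 0.000647, fry adjusted p = 0.0494, adjusted p = 0.351 with an estimated correlation). The lowest p was that of flp-33, which was at 34.5 ± 7.61 and 20.9 ± 1.49. None of 80 ribosomal protein genes passed either way in limma (3 at unadjusted p below 0.05, median -0.13, camera adjusted p = 0.0342, fry adjusted p = 0.294, adjusted p = 0.776 with an estimated correlation), and camera lost the list without eat-2; acs-20 replicate 2 (median -0.06, adjusted p = 0.384) or ptr-8 strain replicate 2 or 3. On the FPKM as deposited the call was lost as well (median -0.02, adjusted p = 0.0741), with 40 of the 80 genes at negative fold changes against 57 after scaling. asp-1, from 5229 ± 481 to 2821 ± 237, fell among 10 intestinal markers, over all genes and adjusted over the list alone (camera adjusted p = 0.477), though with 1 library left out it passed only without eat-2; acs-20 replicate 1 (highest adjusted p 0.162, without ptr-8 strain replicate 3). Its log2 fold change was -0.889 in the main fit and ran from -0.949 to -0.195 over all alternatives (highest limma adjusted p 0.820). No member passed either way in limma among 18 pan-neuronal (camera adjusted p = 0.499), 12 body wall muscle (0.582), 15 pharynx (0.722), 32 oxidative phosphorylation (0.477) and 13 one-carbon and vitamin B12 genes (0.697), with 2, 0, 2, 1 and 0 at unadjusted p below 0.05. Of 9 markers of male neurons none reached the level to be tested.

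All 366 called genes had no overlap between the strains' libraries; among all tested genes 4194, or 27.6%, did not overlap, against 10% by chance. Unadjusted, 3140 genes had p below 0.05. The number of called genes changed with each library left out. Leaving out eat-2; acs-20 replicate 1, 2 or 3 gave 673, 89 and 63 genes, and leaving out ptr-8 strain replicate 1, 2 or 3 gave 88, 165 and 76. Without both the shallowest library and the one with the largest factor 1 gene passed, asp-12. That fit did not test spp-12, ech-9, clec-70, ugt-18, nspg-7.2, clc-11, clec-174, pals-37, sod-5 and bbs-4, which miss the filter on level there. With the adult-stage collagen level as a covariate 16 genes passed. On the FPKM as deposited, which moved the median fold change of all genes to 0.10, 66 genes were higher and 178 lower, so that 27.05% of calls were rises against 14.5% after scaling. Medians of called lists that moved by more than 1.5 times on these values were -0.02 for ribosomal proteins, -0.04 for sphingolipid metabolism, -0.15 for C-type lectins and for cytochrome P450 genes, -0.16 for UDP-glucuronosyltransferases, -0.18 for ER unfolded protein response genes and for hedgehog-related ligands, -0.19 for FMRFamide-like neuropeptides, -0.13 for patched-related genes and 0.28 for germline genes. Camera called 19 of 43 lists (14 lower, 5 higher), fry called 12 (11 lower, 1 higher; 11 in common with camera), and none passed with an estimated correlation (lowest adjusted p 0.275, with 4 lists at unadjusted p below 0.05). The mixed form of fry called 24 lists, the intestinal markers among them (adjusted p = 8.53e-05), and did not call the cuticle collagens (0.0714). When the libraries were split so that the strains were mixed, camera still called 8 to 20 lists.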

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

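Each of the 60 called genes named by the rule kept its sign under each alternative that tested it. Little follows from that, because no called gene overlapped between the strains and most alternatives could hardly turn a sign. Of the 60, 21 passed in each fit with 1 library left out that tested them, while 39 failed at least once. Leaving out 1 library gave 63 to 673 genes, 62 to 324 genes at 2-fold or more and 14 to 21 lists; these fits have fewer residual degrees of freedom. Median-of-ratios scaling gave 360 genes (360 shared with the 366), upper-quartile scaling 281 (279 shared), a pseudocount of 0.1 gave 312 (310 shared) and no filter 258 (242 shared). A replicate block gave 163 genes (134 shared) and 144 at 2-fold or more. Whether the replicate numbers pair the samples is not known. Same-number correlations of the centred levels were 0.249, 0.0473 and 0.0344, all positive and the first the highest of any pair. eat-2; acs-20 replicate 2 correlated best with ptr-8 strain replicate 3 (0.154), so the correlations do not settle it. Of alternatives chosen after the data were seen, FPKM as deposited gave 244 genes (170 shared), voom on implied fragments 67 (66 at 2-fold or more; 66 shared), the adult-stage collagen covariate 16 and 16, and leaving out both libraries that stand apart 1 and 1. The covariate, which spends 1 residual degree of freedom, turned the medians of furrow collagens to 0.50, major sperm proteins to -0.55 and sperm genes to -0.10. The medians of 9 further lists, none called by camera, changed sign with it, among them lipases, molting genes, epidermis and pharynx. For lists, fry called 12 and camera with an estimated correlation 0 (4 at unadjusted p below 0.05), against 19. Where not stated, the cause was not tested. The DESeq2 and edgeR alternatives planned were not run because the deposited files hold FPKM and no counts. The shallowest library, at 0.569 times the depth of the first, had a median interval half-width of 14.7% of the FPKM, so small changes in low genes are limited by its counting error.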

Other observations

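The gene class test, the stage covariate and the ribosomal RNA comparison below were chosen after the result was seen, and so were the genes named here; the linkage test and the splits were planned. Gene classes by name prefix (364 classes, 8273 genes) were tested for an excess of called genes. The counts rest on the 366 calls and were not repeated under the alternatives, and in the spp, clc and fbxa classes most genes did not pass. Among aspartyl proteases 6 of 11 tested genes fell (Fisher's exact test, adjusted p = 4.45e-06), among them abundant members: asp-3 from 2158 ± 172 to 903 ± 69.5 and asp-6 from 5054 ± 582 to 1855 ± 389. Of 25 saposin-like genes 8 fell (adjusted p = 4.16e-06), spp-5 from 13293 ± 1049 to 5038 ± 971. spp-9 was at 3.48, 6.30 and 11.3 and spp-21 at 1.98, 2.45 and 2.23 in eat-2; acs-20, and both are listed at 0 in all ptr-8 libraries. Of 22 claudin-like clc genes 6 fell (adjusted p = 0.000399), including clc-1 (224 ± 23.004 to 73.8 ± 7.50) and clc-19 (50.2 ± 5.40 to 9.44 ± 1.56). Of 131 fbxa genes 11 fell (adjusted p = 0.00595).

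Other called genes, in no list here, are given singly. gba-1 (62.9 ± 3.81 to 26.3 ± 0.978, adjusted p = 0.00447) and gba-4 (75.4 ± 23.03 to 18.2 ± 2.42, adjusted p = 0.0213), for glucosylceramidases, fell, as did ctsa-1.2 and lgmn-1 (adjusted p = 0.0222 and 0.0305). The lysosomal nuclease gene nuc-1 rose from 46.9 ± 7.40 to 106 ± 8.64 (adjusted p = 0.0169), the ferritin gene ftn-1 from 37.6 ± 2.93 to 83.0 ± 14.99 (adjusted p = 0.0247), and the cystathionine enzymes' genes cbl-1 and cth-2 rose by 0.95 and 0.98 on the log2 scale. C08E3.1 and C08E3.13, 2 genes of chromosome II, fell by 4.85 and 4.40 on the log2 scale. ZK688.4 was listed at 0 in the eat-2; acs-20 libraries and was at 57.1, 91.0 and 104 in the ptr-8 strain (adjusted p = 0.000631). For this gene, spp-9 and spp-21, as for spp-12, FPKM does not show whether a gene listed at 0 is silent or missing from that strain's genome. Called genes were most frequent on chromosome V (3.72% of 3066 tested, Fisher's exact test, adjusted p = 2.73e-06) and least on chromosome I (1.13% of 2468, adjusted p = 3.82e-06). In the same test chromosomes IV (3.33%, adjusted p = 0.00202), III (1.75%, 0.0329) and X (1.71%, 0.0329) passed too, and chromosome II did not (2.29%, 0.724). The test takes genes as independent, but many called genes are related copies on 1 chromosome, such as histone genes on chromosome V, so these p-values are too low.

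The first pattern is the fall of immune genes together with the rise of yolk genes. A difference in developmental stage at collection could give it, since the mean of the 4 genes listed as adult-stage collagens was on average higher in the ptr-8 strain. col-63 was not higher (log2 fold change -0.22), but whether it marks the same stage as the others was not tested. With the mean of all 4 as a covariate the median moved from -1.43 to -1.26 for immune effectors (fry adjusted p 0.0128 to 0.115), from -0.24 to -0.22 for C-type lectins (0.00411 to 0.0814) and from 2.78 to 1.71 for vitellogenins (0.0494 to 0.373), so fry no longer called any of these 3 lists. Camera called 16 lists in that fit, and 13 of these, whatever their direction, were among the 19 it called without the covariate. Other lists called by camera shrank more: oogenesis genes from 0.77 to 0.28, hedgehog-related ligands from -0.28 to -0.08 and patched-related genes from -0.21 to -0.07, with ER unfolded protein response genes from -0.29 to -0.16 and fatty acid binding proteins from -0.45 to -0.26. Stage and strain cannot be told apart for the 3 lists, because the marker partly follows the strains and the fit has 3 residual degrees of freedom. The same limit holds for pals genes, though they kept both their median (-0.65 to -0.59) and their fry call (adjusted p = 0.0396). It also holds for the 16 genes that passed with the covariate, asp-12, ech-9, clec-70, spp-12 and dod-22 among them.

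The second pattern is the fall of histone genes. A lower yield of RNA without a poly(A) tail in the ptr-8 libraries would lower ribosomal RNA as well. The 3 tested ribosomal RNA genes were not lower, with a median log2 fold change of 0.17 (SE 0.180, 0.187 and 0.268). That does not decide the question, because the selection step is not given in the sources used here. What the ribosomal RNA level measures is therefore unknown. A stage difference stays open: with the covariate the list's median moved from -0.71 to -0.61 and its fry adjusted p from 0.0189 to 0.200. A change in the number of dividing cells was not tested.

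The third is background linked to ptr-8. Within 2 Mb of it 21 of 694 tested genes were called (3.03%), against 37 of 1877 on the rest of chromosome II (1.97%), with one-sided Fisher's exact p = 0.0764. Linked variants and ptr-8 itself cannot be told apart for genes near it, because the samples hold no second allele or rescue.

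The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 366 genes and 230 at 2-fold or more, the highest other split 2 of each, so the real count was reached in 1 split. For lists the real split gave 19 and the others 8 to 20, and 3 of the 10 splits gave as many. Camera at the preset correlation of 0.01 thus called many lists with the strains mixed, so its p-values alone do not tie a list to strain. Correlations estimated from the data were 0.918 for vitellogenins, 0.905 for oogenesis genes and 0.190 for histones, but 0.0143 for C-type lectins.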
